A study of Danio rerio with 12 samples.

How the data were processed

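RNA was taken from pools of 10 whole larvae at 119 hours post-fertilization, and libraries were made from 100 ng of RNA with an integrity number above 7, using poly-A selection, a TruSeq V2 kit and 12 PCR cycles, per the labels' protocols. There was 1 file per library for each of the 12 libraries. Each file held raw read counts for 32105 Ensembl gene IDs, as deposited by the authors. Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and trimmed with Trimmomatic 0.36, and the genome build was GRCz10. The aligner, the counting tool and its handling of strand and of reads that match several genes are not given in the sources used here. Reads shared by near-identical genes could therefore have been split, dropped or counted more than once, which bears on the hsp70, ferritin and GGACT genes.

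Groups were taken from the sample titles, which name the genotype and the iAs dose. Library totals ran from 28909467 to 43759270 counts, and the most abundant 10 genes held 8.80 to 9.90% of each. At such totals the counting error of a well-expressed gene is small beside the spread between libraries, which was 9.00% as a common biological coefficient of variation. Replicates of a group differed by more than sampling noise (chi-square over degrees of freedom from 5.18 to 21.5 for genes with at least 20 counts in a pair), and 0 pairs were identical. The sample titles end in cl1, cl2 or cl3, which the labels do not explain and which might stand for clutches, in which case a paired fit would apply. As separate clutches are not stated, the p-values measure the spread between these samples, which may be partly technical. A single run label covers all libraries, so no batch was compared.

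Gene symbols came from a table of Ensembl IDs, which named 26269 of the 32105 IDs. It gave 1632 symbols to more than 1 ID, and the Ensembl ID is printed for those. Of 923 entries in the 30 gene lists written before the data were examined, 862 were matched to a gene, 677 by the exact symbol. The lists cover arsenic handling, stress responses, metabolism, cell types and tissues.

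Genes were kept with filterByExpr at a minimum count of 10, which left 23096. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) to the 4 groups over all 12 libraries, so that the groups share 1 estimate of the spread. The contrasts were iAs in wild type, iAs in the mutant, mutant against wild type without and with iAs, and the difference of the responses (interaction). Every adjusted p is a Benjamini-Hochberg value over the genes or lists tested in its contrast, and a gene or list is called below 0.05. SE is the standard error of the log2 fold change, fold values are its antilog, and levels are in CPM from edgeR after scaling. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. The list medians were also taken with members at 0 counts set to their bound, and 0 of 120 medians differed at 2 decimals. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio has an exact 95% interval. Floors and intervals cover counting error only. R was 4.3.3, and tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

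The text names genes by a rule written before the data were examined. It names as3mt, HMOX1, GCLM, MT1X, hsp70l, ATF3, CYP1A1 and fabp10a in every contrast. It adds the 5 largest rises and the 5 largest falls per contrast among called genes with a symbol that is not a clone or locus name, a mean of at least 5 CPM and no overlap between the groups, a condition not set for the interaction. From each list it takes up to 3 called members with the largest change. Genes named in 1 contrast may be given in another. Among the genes that meet this rule, 1 is withheld and not reported here.

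The analysis was tested on simulated counts with known changes before use. For iAs in wild type, on 22463 genes, 42.9%, 85.5% and 96.8% of the genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 4.08% of calls were false. For the interaction, on 22449 genes, these were 28.1%, 72.3% and 95.3%, with 3.82% false. Of the 30 lists, 0 were called for the first and 1 for the second. The changed genes were drawn over all genes, list members included, and each gene was simulated independently. The simulation therefore does not show how often lists of correlated genes are called falsely.

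Alternatives were other scaling factors (DESeq2 size factors, library size alone), DESeq2 1.42.0 in place of edgeR, no filter or a mean count of at least 50, only the libraries compared, a fold threshold of 2, the replicate number as a block, each library left out in turn, and camera on ranks. The share of calls near as3mt on its chromosome was planned and left out, since positions could be matched by name for 76.7% of the tested genes, under the 80% needed.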

Results

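The data were RNA-seq read counts from pools of 10 whole zebrafish larvae collected at 119 hours post-fertilization, that is at 5 days. Wild-type larvae of the TAB14 strain were compared with larvae homozygous for an 8 bp deletion in exon 3 of as3mt, which introduces a premature stop. The gene encodes arsenite methyltransferase, the enzyme that adds methyl groups to inorganic arsenic. Each genotype was left untreated or kept in 1 mM inorganic arsenic (iAs) from 6 hours post-fertilization, with 20 embryos per well in 10 mL. Each of the 4 groups held 3 libraries, 12 in all. The mutant line came from another background than the wild type (ABNYU), so genotype and strain went together in every comparison. Library totals ran from 28909467 to 43759270 counts. Mitochondrial transcripts took 4.53% (SD 0.0770, n = 3), 4.24% (SD 0.0417, n = 3), 4.39% (SD 0.0910, n = 3) and 4.16% (SD 0.0980, n = 3) of the counts in untreated and treated wild type and in the untreated and treated mutant. Some zebrafish genes carry a human-style symbol in the name table, such as HMOX1 for hmox1a and MT1X for mt2.

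The targeted gene was measured first. The transcript of as3mt (AS3MT, ENSDARG00000027572) stood at 16.1 ± 1.57 CPM (counts scaled to library size; SD, n = 3) in untreated wild type, 9.81 ± 0.103 (SD, n = 3) in treated wild type, 9.55 ± 0.352 (SD, n = 3) in the untreated mutant and 3.28 ± 0.245 (SD, n = 3) in the treated mutant. By library, untreated wild type held 14.3, 16.8 and 17.2 CPM, treated wild type 9.77, 9.73 and 9.93, the untreated mutant 9.21, 9.91 and 9.52 and the treated mutant 3.02, 3.31 and 3.51. AS3MT was 1.68-fold lower in the untreated mutant (log2 fold change -0.75, SE 0.10, adjusted p = 3.9e-05) and 2.99-fold lower under iAs (-1.58, SE 0.11, adjusted p = 3.2e-09). Exposure lowered it 1.64-fold in wild type (-0.71) and 2.91-fold in the mutant (-1.54), and the drop was larger in the mutant (interaction -0.83, adjusted p = 3.7e-04). A count per gene also takes in reads outside the deletion, so the level does not show whether protein was made.

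**Figure D1:**
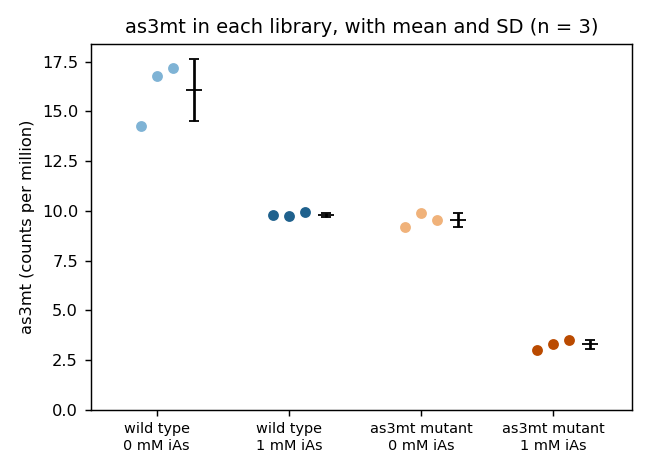
Level of as3mt in CPM for each of the 12 libraries, by genotype and iAs dose; points are libraries and bars show the mean and SD of 3. Every treated mutant library lies between 3.02 and 3.51, below every library of the other 3 groups.

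On the principal components of log2 CPM over 23096 tested genes, the libraries fell into their 4 groups. The first component took 56.8% of the variance and placed untreated wild type lowest, then the untreated mutant, treated wild type and the treated mutant. The second took 21.2% and set the treated wild type against the untreated mutant.

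**Figure D2:**
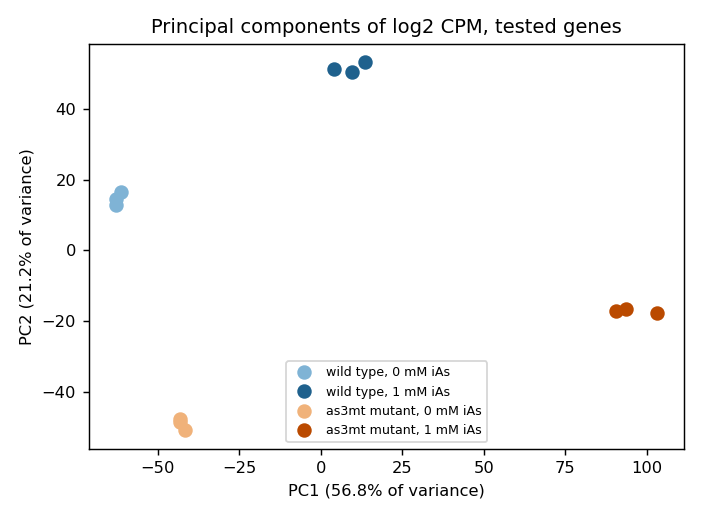
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM (axes in score units, with the percent of variance of each); points are libraries, coloured by group. Libraries of a group lie together, and the treated mutant is farthest from its untreated group along the first component, which holds 56.8% of the variance.

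The first comparison asked how wild-type larvae responded to iAs. Wild-type larvae in 1 mM iAs raised genes for oxidant defence, protein folding, and metal and iron handling, and lowered genes of the gut. Metallothionein MT1X, a metal-binding protein, rose 26.0-fold from 68.4 ± 1.27 to 1782 ± 174 CPM (SD, n = 3 per group). The inducible chaperone gene hsp70l rose 29.7-fold (log2 fold change 4.89, SE 0.58, n = 3 per group), and GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 4.53-fold (2.18, SE 0.07). The largest rises by the naming rule were hspa1b, 147-fold, ptgr1.2, a prostaglandin reductase, 129-fold, fthl28, a ferritin heavy chain gene, 88.8-fold, CYB561A3 (ENSDARG00000028257), a cytochrome b561 family gene, 87.9-fold, and hsp70.3, 51.2-fold. By the same rule, which asks for a mean of at least 5 CPM, the largest falls were MEP1B (ENSDARG00000037533), a brush-border metalloprotease, 95.7-fold, the intestinal sphingomyelinase ENPP7 (ENSDARG00000053526), 13.4-fold, the fetuin genes ahsg1, 12.5-fold, and ahsg2, 9.81-fold, and rca2.2, 12.1-fold. The hsp70 genes are close copies of one another, as are the ferritin genes, so how reads were split among them is uncertain. CYB561A3 was at 136-fold without replicate 2 of the untreated wild type. hspa1b was at 92.3-fold, hsp70.3 at 31.3-fold and MEP1B at 254-fold without replicate 1 of the treated wild type.

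In the Nrf2 and glutathione list, 28 of 35 genes rose and 5 fell (29 and 5 adjusted over the list alone, adjusted p = 1.7e-82, and adjusted p = 2.9e-04 with an estimated correlation). The list had a median log2 fold change of 1.65. Its largest changes were in the autophagy receptor SQSTM1, 25.5-fold higher, the peroxiredoxin prdx1 (ENSDARG00000058734), 22.2-fold, and the glutathione transferase gstp1.2, 10.3-fold, while haem oxygenase HMOX1 rose 1.53-fold. Of the cytosolic heat shock list, 27 of 31 genes rose and 1 fell (28 and 1 adjusted over the list alone, adjusted p = 1.6e-29, and adjusted p = 0.00866 with an estimated correlation), with a median of 1.32. Among metal and iron genes, 10 of 20 genes rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 6.9e-19, and adjusted p = 2.7e-04 with an estimated correlation), with a median of 0.47. They were led by fthl28, fthl31, 31.9-fold higher, and MT1X. In the integrated stress response list 17 of 29 genes rose and 5 fell (18 and 6 adjusted over the list alone, adjusted p = 0.00110, and adjusted p = 0.279 with an estimated correlation). Here the stress transcription factor ATF3 rose 5.83-fold and the serine synthesis enzyme PSAT1 2.86-fold. For the unfolded protein response of the endoplasmic reticulum, 17 of 30 genes rose and 2 fell (17 and 2 adjusted over the list alone, adjusted p = 0.00340, and adjusted p = 0.364 with an estimated correlation), and the thiol oxidase ERO1A rose 2.43-fold. In acute inflammation 21 of 31 genes rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 1.7e-06, and adjusted p = 0.312 with an estimated correlation). Among them were the chemokine cxcl18b, 16.6-fold higher, and the transcription factor FOSL1, 15.1-fold. In the interferon response 12 of 23 genes rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 0.00283, and adjusted p = 0.313 with an estimated correlation), and the ubiquitin-like isg15 rose 8.41-fold. In p53 and DNA damage 14 of 28 genes rose and 7 fell (14 and 7 adjusted over the list alone, adjusted p = 0.00148, and adjusted p = 0.332 with an estimated correlation). In ribosome biogenesis 15 of 29 genes rose and 2 fell (15 and 2 adjusted over the list alone, adjusted p = 0.0178, and adjusted p = 0.353 with an estimated correlation).

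Most lists of differentiated cell types were called lower in wild type with the preset correlation, and with an estimated one the enterocyte list alone. The skeletal muscle, ionocyte and leukocyte lists were not called. Counts from whole larvae, here and in every comparison, cannot tell a change in cell numbers from a change in RNA per cell. Of the enterocyte list, 27 of 34 genes fell and 2 rose (27 and 2 adjusted over the list alone, adjusted p = 1.4e-28, and adjusted p = 0.00486 with an estimated correlation), with a median of -1.13. The cholesterol transporter NPC1L1 fell 7.25-fold, the chitinase chia.1 5.21-fold and the amino acid transporter SLC6A19 (ENSDARG00000018621) 5.04-fold. In the hepatocyte list 26 of 42 genes fell and 7 rose (27 and 7 adjusted over the list alone, adjusted p = 1.6e-09, and adjusted p = 0.193 with an estimated correlation). The liver fatty acid binding protein fabp10a fell 2.02-fold, from 326 ± 30.0 to 161 ± 24.8 CPM (SD, n = 3 per group). The dioxin-inducible monooxygenase CYP1A1, a member of the xenobiotic metabolism list, fell 2.88-fold (-1.53, SE 0.08). That list was not called, as 11 of 25 genes fell and 8 rose (12 and 8 adjusted over the list alone, adjusted p = 0.0546). Of exocrine pancreas genes, 23 of 24 genes fell and 0 rose (23 and 0 adjusted over the list alone, adjusted p = 1.1e-10, and adjusted p = 0.236 with an estimated correlation), with a median of -0.76. Among cartilage and bone genes 29 of 33 genes fell and 0 rose (29 and 0 adjusted over the list alone, adjusted p = 1.7e-14, and adjusted p = 0.142 with an estimated correlation), and the cartilage collagen COL11A2 fell 1.96-fold. Among neuron and glia genes 35 of 40 genes fell and 0 rose (36 and 2 adjusted over the list alone, adjusted p = 2.3e-14, and adjusted p = 0.137 with an estimated correlation), with the myelin gene mbpa 2.68-fold lower. Among photoreceptor genes 33 of 46 genes fell and 1 rose (34 and 1 adjusted over the list alone, adjusted p = 1.8e-07, and adjusted p = 0.207 with an estimated correlation), with the cone arrestin ARR3 (ENSDARG00000098475) 2.41-fold lower. Among lens genes 10 of 30 genes fell and 2 rose (10 and 2 adjusted over the list alone, adjusted p = 0.0393, and adjusted p = 0.508 with an estimated correlation). Of pigment cell genes 7 of 22 genes fell and 0 rose (7 and 0 adjusted over the list alone, adjusted p = 0.00287, and adjusted p = 0.321 with an estimated correlation). Clock genes were called lower as a list, as 20 of 38 genes fell and 9 rose (20 and 9 adjusted over the list alone, adjusted p = 0.00110, and adjusted p = 0.279 with an estimated correlation). For gluconeogenesis and glucocorticoid targets 11 of 20 genes fell and 2 rose (11 and 3 adjusted over the list alone, adjusted p = 0.00219, and adjusted p = 0.277 with an estimated correlation). In cholesterol and fatty acid synthesis 21 of 35 genes fell and 6 rose (21 and 6 adjusted over the list alone, adjusted p = 0.00110, and adjusted p = 0.353 with an estimated correlation). Erythrocyte genes went up, where 12 of 20 genes rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.00110, and adjusted p = 0.207 with an estimated correlation). Arsenic transport and conjugation was not called, with a median of -0.31 and a mean of 0.08, and there 6 of 17 genes rose and 8 fell (6 and 9 adjusted over the list alone, adjusted p = 0.476). Within it the omega-class glutathione transferases gsto2 and gsto1 rose 19.5-fold and 9.02-fold, and the phosphate transporter SLC34A2 (ENSDARG00000012903) fell 4.54-fold.

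Over all genes, edgeR called 10354 of 23096 in wild type (44.8%), 5230 higher and 5124 lower, of which 1695 changed by 2-fold or more. Library sizes alone gave 5284 and 4911, and DESeq2 size factors 4917 and 5377. Camera called 21 of the 30 lists, and 4 of them (Nrf2 and glutathione, cytosolic heat shock, metal and iron, enterocyte) with a correlation between genes estimated from the data.

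The second comparison asked the same of the as3mt mutant. Mutant larvae in iAs raised genes for oxidant defence and for metal and iron handling, and lowered genes of the gut. Lists of inflammation, pancreas, liver, eye, nerve and the cell cycle were called with the preset correlation alone (adjusted p from 0.0505 for neuron and glia to 0.253 for hepatocyte with an estimated correlation). MT1X rose 61.2-fold from 59.8 ± 8.27 to 3661 ± 301 CPM (SD, n = 3 per group), hsp70l rose 214-fold (log2 fold change 7.74, SE 0.57), ATF3 30.2-fold and HMOX1 3.71-fold. The liver gene fabp10a fell 13.2-fold, from 247 ± 28.4 to 18.7 ± 7.75 CPM (SD, n = 3 per group), and CYP1A1 fell 4.74-fold. The largest rises by the naming rule, at a mean of at least 5 CPM, were the leptin gene lepb, 394-fold, hsp70l, hsp70.1, 128-fold, hsp70.3, 122-fold, and CYB561A3 (ENSDARG00000028257), 112-fold. The largest falls by this rule were ahsg2, 127-fold, the bile salt export pump ABCB11 (ENSDARG00000070078), 37.4-fold, the carboxypeptidase cpo, 35.3-fold, the nuclear receptor nr5a5, 34.8-fold, and lactase LCT (ENSDARG00000060671), 30.3-fold. Below that mean, MEP1B (ENSDARG00000037533) had 0 counts in all 3 treated mutant libraries and was at least 140.4-fold lower than in the untreated mutant, taking a floor of 3 counts over the group. lepb was at 829-fold without replicate 1 of the untreated mutant. hsp70l was at 101-fold, hsp70.1 at 64.2-fold and hsp70.3 at 74.0-fold without replicate 1 of the treated mutant. ahsg2 was at 264-fold without replicate 2 of the treated mutant. ABCB11 was at 57.2-fold without replicate 3 of the treated mutant.

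Several stress lists were called higher in the mutant as well with the preset correlation, and of these Nrf2 and glutathione and metal and iron with an estimated one. In Nrf2 and glutathione 27 of 35 genes rose and 5 fell (28 and 5 adjusted over the list alone, adjusted p = 1.4e-32, and adjusted p = 0.00441 with an estimated correlation), with a median of 1.51. Its members SQSTM1, prdx1 (ENSDARG00000058734) and GCLM rose 28.2-fold, 21.9-fold and 3.99-fold. In cytosolic heat shock 27 of 31 genes rose and 1 fell (27 and 1 adjusted over the list alone, adjusted p = 3.6e-15, and adjusted p = 0.0505 with an estimated correlation), with a median of 1.39. Among metal and iron genes 13 of 20 genes rose and 5 fell (13 and 5 adjusted over the list alone, adjusted p = 1.7e-08, and adjusted p = 0.00441 with an estimated correlation). In acute inflammation 30 of 31 genes rose and 0 fell (30 and 0 adjusted over the list alone, adjusted p = 1.3e-11, and adjusted p = 0.219 with an estimated correlation), with a median of 2.43. They included FOSL1, 96.9-fold higher, and the cytokine gene il11a, 59.7-fold. In p53 and DNA damage 18 of 28 genes rose and 4 fell (18 and 4 adjusted over the list alone, adjusted p = 4.9e-06, and adjusted p = 0.219 with an estimated correlation), and the growth arrest gene GADD45B (ENSDARG00000027744) rose 5.76-fold. In the integrated stress response 15 of 29 genes rose and 7 fell (16 and 7 adjusted over the list alone, adjusted p = 5.8e-04, and adjusted p = 0.240 with an estimated correlation). Here the phosphatase subunit ppp1r15a rose 7.12-fold and the transcription factor CEBPB 6.82-fold. In the interferon response 13 of 23 genes rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.345 with an estimated correlation). In ribosome biogenesis 22 of 29 genes rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 8.6e-05, and adjusted p = 0.219 with an estimated correlation). The unfolded protein response list was not called, as 12 of 30 genes rose and 3 fell (12 and 3 adjusted over the list alone, adjusted p = 0.0924), though ERO1A rose 8.46-fold. FOSL1 was at 157-fold without replicate 3 of the untreated mutant. FOSL1 was at 58.7-fold and il11a at 32.1-fold without replicate 1 of the treated mutant.

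Of the enterocyte list in the mutant, 31 of 34 genes fell and 3 rose (31 and 3 adjusted over the list alone, adjusted p = 1.3e-39, and adjusted p = 0.00441 with an estimated correlation), with a median of -2.39. The peptide transporter SLC15A1 (ENSDARG00000100315) fell 26.3-fold, chia.1 23.0-fold and the meprin mep1a.1 16.5-fold. Of exocrine pancreas genes 24 of 24 genes fell and 0 rose (24 and 0 adjusted over the list alone, adjusted p = 4.5e-14, and adjusted p = 0.211 with an estimated correlation), with a median of -1.65, and the elastase ela2 fell 8.12-fold from 687 ± 58.2 to 84.4 ± 17.2 CPM (SD, n = 3 per group). Among photoreceptor genes 39 of 46 genes fell and 3 rose (39 and 3 adjusted over the list alone, adjusted p = 2.6e-13, and adjusted p = 0.108 with an estimated correlation), and the guanylate cyclase activator guca1d fell 17.2-fold. Among lens genes 27 of 30 genes fell and 0 rose (27 and 0 adjusted over the list alone, adjusted p = 3.9e-06, and adjusted p = 0.219 with an estimated correlation). Among neuron and glia genes 36 of 40 genes fell and 2 rose (36 and 2 adjusted over the list alone, adjusted p = 4.1e-22, and adjusted p = 0.0505 with an estimated correlation), and the myelin gene mbpa fell 23.2-fold. In the cell cycle list 27 of 38 genes fell and 1 rose (27 and 1 adjusted over the list alone, adjusted p = 1.5e-05, and adjusted p = 0.237 with an estimated correlation), and the replication helicase genes MCM5 and MCM2 fell 2.60-fold and 2.48-fold. Among hepatocyte genes 27 of 42 genes fell and 9 rose (27 and 9 adjusted over the list alone, adjusted p = 1.0e-05, and adjusted p = 0.253 with an estimated correlation). Among cartilage and bone genes 27 of 33 genes fell and 0 rose (27 and 1 adjusted over the list alone, adjusted p = 5.6e-07, and adjusted p = 0.240 with an estimated correlation). Of circadian clock genes 22 of 38 genes fell and 12 rose (22 and 12 adjusted over the list alone, adjusted p = 0.0214, and adjusted p = 0.393 with an estimated correlation). For fatty acid oxidation 21 of 33 genes fell and 6 rose (22 and 6 adjusted over the list alone, adjusted p = 0.0214, and adjusted p = 0.345 with an estimated correlation). Erythrocyte genes were not called as a list, where 11 of 20 genes fell and 2 rose (11 and 2 adjusted over the list alone, adjusted p = 0.0574).

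In all, edgeR called 14695 of 23096 genes in the mutant (63.6%), 7172 higher and 7523 lower, of which 4747 changed by 2-fold or more. With library sizes alone 6284 were higher and 8189 lower, and with DESeq2 size factors 7371 and 7373. Camera called 18 of 30 lists, and 3 with an estimated correlation (Nrf2 and glutathione, metal and iron, enterocyte).

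**Figure D3:**
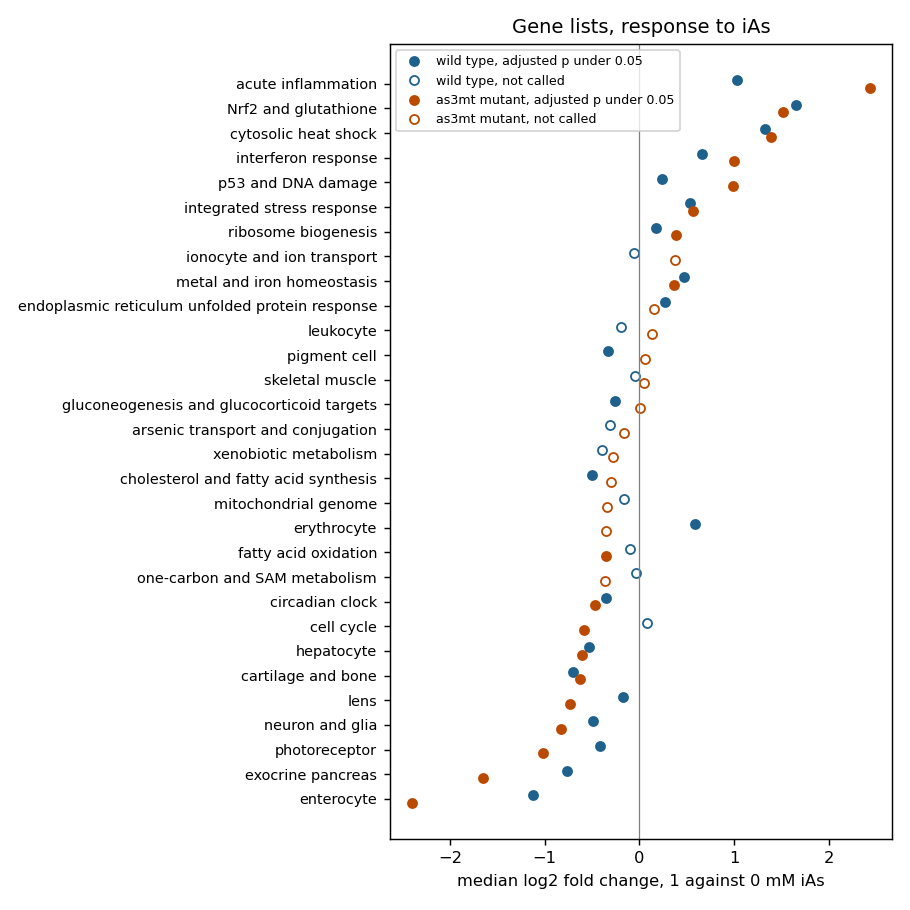
Median log2 fold change between 1 and 0 mM iAs of the measured members of each of the 30 gene lists (horizontal axis), in wild type (blue) and the as3mt mutant (orange), sorted by the mutant; filled points are lists called by camera with the preset correlation at an adjusted p under 0.05, open points are not called. The enterocyte median lies at -1.13 in wild type and -2.39 in the mutant, and the Nrf2 and glutathione median at 1.65 and 1.51.

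The third comparison set the untreated genotypes side by side. Untreated mutants differed from wild type in fewer genes, and none of HMOX1, GCLM, MT1X, hsp70l, ATF3, CYP1A1 and fabp10a was called (adjusted p from 0.165 for fabp10a to 0.897 for ATF3). With only the 6 untreated libraries in the fit, fabp10a was called, at an adjusted p of 0.00350. The differences named next are the largest by the naming rule, among genes with a mean of at least 5 CPM. CCDC134 (ENSDARG00000103285) was 258-fold lower, with 1, 1 and 2 counts in the mutant libraries against 353, 352 and 333 in wild type. The elastase-like gene ela2l was 38.0-fold lower, the C-reactive protein family gene crp5 10.4-fold, the protocadherin pcdh1g22 9.61-fold and the chitinase chia.3 5.83-fold. The cardiac-type actin actc1c was 20.7-fold higher, ms4a17a.9 12.1-fold, PIGP, of glycolipid anchor synthesis, 8.07-fold, urokinase PLAU (ENSDARG00000039145) 4.61-fold, and the nuclear receptor NR0B2 (ENSDARG00000044685) 3.78-fold. MT1X was 1.23-fold lower in the mutant (adjusted p = 0.0279, called) without replicate 3 of the untreated mutant.

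Among exocrine pancreas genes of the untreated mutant, 19 of 24 genes were lower and 1 higher (20 and 1 adjusted over the list alone, adjusted p = 3.6e-23, and adjusted p = 0.254 with an estimated correlation), with a median of -0.49. The secretory granule gene SYCN (ENSDARG00000090899) was 3.09-fold lower. Of ribosome biogenesis genes 23 of 29 genes were lower and 0 higher (25 and 0 adjusted over the list alone, adjusted p = 7.2e-17, and adjusted p = 0.0577 with an estimated correlation), with a median of -0.33, including NOP10, 2.04-fold lower, and POLR1A, 1.40-fold. Of photoreceptor genes 20 of 46 genes were lower and 2 higher (26 and 4 adjusted over the list alone, adjusted p = 9.1e-07, and adjusted p = 0.492 with an estimated correlation). In the integrated stress response list 10 of 29 genes were higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 2.5e-06, and adjusted p = 0.345 with an estimated correlation). Its largest differences were in the serine synthesis genes PSAT1, 2.17-fold higher, and PHGDH, 1.92-fold, and the mitochondrial folate gene ALDH1L2, 1.61-fold. In the cell cycle list 14 of 38 genes were higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 7.5e-05, and adjusted p = 0.492 with an estimated correlation). In the erythrocyte list 5 of 20 genes were higher and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.492 with an estimated correlation). In cholesterol and fatty acid synthesis 4 of 35 genes were lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.0218, and adjusted p = 0.987 with an estimated correlation). The one-carbon list was not called, as 6 of 26 genes were higher and 6 lower (6 and 6 adjusted over the list alone, adjusted p = 0.793). In it the mitochondrial folate gene MTHFD1L was 3.47-fold higher and the methionine adenosyltransferase MAT2A (ENSDARG00000037121), which makes the methyl donor, 2.62-fold lower. The circadian clock list was not called either, as 10 of 38 genes were lower and 5 higher (14 and 8 adjusted over the list alone, adjusted p = 0.465), with the period gene PER2 2.22-fold lower and the nuclear receptor rorcb 2.04-fold higher.

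In this comparison edgeR called 3110 of 23096 genes (13.5%), 1534 higher and 1576 lower in the mutant, and 794 differed by 2-fold or more. With library sizes alone in place of TMM factors 1727 were higher and 1326 lower, while with DESeq2 size factors these were 1418 and 1700 and with the DESeq2 test 1547 and 1853. Camera called 7 of 30 lists with the preset correlation and 0 with the estimated one (3 at an unadjusted p under 0.05, and 7 with a rank-based camera, smallest adjusted p = 0.0577). Without replicate 2 of the untreated mutant 2097 genes were called.

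The genotypes were then compared under 1 mM iAs. With the preset correlation, lists of inflammation, the integrated stress response and p53 were called higher in treated mutants than in treated wild type, and lists of gut, pancreas, eye, nerve, red blood cells and the cell cycle lower. None of them was called with an estimated correlation (smallest adjusted p = 0.0505), and the Nrf2 and heat shock lists were not called with either. Here hsp70l was 12.6-fold higher in the mutant, at 726 ± 666 against 57.7 ± 23.7 CPM (SD, n = 3 per group), ATF3 5.42-fold higher (log2 difference 2.44, SE 0.19), HMOX1 2.20-fold and MT1X 2.05-fold. The liver gene fabp10a was 8.66-fold lower and CYP1A1 1.77-fold lower, and GCLM was not called (-0.14, SE 0.06, adjusted p = 0.0666, and -0.19 with adjusted p = 0.0125 and called with library sizes alone). The largest differences upward by the naming rule were GGACT (ENSDARG00000038248), actc1c, 45.5-fold, the yolk protein gene vtg1, 14.8-fold, the immediate early gene FOS (ENSDARG00000031683), 14.2-fold, and the neuropeptide gene CARTPT (ENSDARG00000035852), 13.3-fold. There are 3 gene IDs with the symbol GGACT, so how reads were assigned among them is uncertain. ENSDARG00000038248 had 1 count over the 3 treated wild-type libraries and 1328 over the 3 treated mutant libraries. The ratio was 1544 (exact 95% counting interval 277 to 61009, which covers counting error only). The 1 count was in replicate 1 of the treated wild type, and without that library the group had 0 counts. Downward they were CCDC134 (ENSDARG00000103285), the cadherin cdh29, 156-fold, ela2l, 81.0-fold, cpo, 15.7-fold, and ABCB11 (ENSDARG00000070078), 14.7-fold. CCDC134 had 3 counts in the treated mutant and 1412 in treated wild type, a ratio of 405 (exact 95% counting interval 138 to 1966). GCLM was 1.16-fold lower in the mutant (adjusted p = 0.0142, called) without replicate 2 of the treated wild type. hsp70l was at 5.96-fold, actc1c at 30.2-fold and FOS at 5.76-fold without replicate 1 of the treated mutant. actc1c was at 68.6-fold without replicate 2 of the treated mutant. vtg1 was at 8.01-fold, cdh29 at 346-fold and ABCB11 at 22.5-fold without replicate 3 of the treated mutant.

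In acute inflammation 29 of 31 genes were higher and 0 lower (29 and 0 adjusted over the list alone, adjusted p = 3.5e-10, and adjusted p = 0.225 with an estimated correlation) in the treated mutant, with a median of 1.64, and FOSL1 was 7.44-fold higher. In the integrated stress response 18 of 29 genes were higher and 5 lower (19 and 5 adjusted over the list alone, adjusted p = 3.2e-06, and adjusted p = 0.180 with an estimated correlation). In p53 and DNA damage 20 of 28 genes were higher and 5 lower (20 and 5 adjusted over the list alone, adjusted p = 3.1e-04, and adjusted p = 0.326 with an estimated correlation). In the leukocyte list 17 of 34 genes were higher and 7 lower (17 and 7 adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.0982 with an estimated correlation). For gluconeogenesis and glucocorticoid targets 12 of 20 genes were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.00824, and adjusted p = 0.326 with an estimated correlation). Among skeletal muscle genes 16 of 38 genes were higher and 3 lower (17 and 3 adjusted over the list alone, adjusted p = 0.00942, and adjusted p = 0.554 with an estimated correlation). Of pigment cell genes 12 of 22 genes were higher and 6 lower (13 and 6 adjusted over the list alone, adjusted p = 0.0403, and adjusted p = 0.554 with an estimated correlation). Among enterocyte genes 28 of 34 genes were lower and 3 higher (29 and 3 adjusted over the list alone, adjusted p = 4.7e-21, and adjusted p = 0.0505 with an estimated correlation), with a median of -0.97, and SLC15A1 (ENSDARG00000100315) was 5.46-fold lower. Of exocrine pancreas genes 21 of 24 genes were lower and 0 higher (22 and 0 adjusted over the list alone, adjusted p = 9.4e-24, and adjusted p = 0.0982 with an estimated correlation). Of photoreceptor genes 38 of 46 genes were lower and 3 higher (38 and 4 adjusted over the list alone, adjusted p = 3.0e-17, and adjusted p = 0.0982 with an estimated correlation). Of neuron and glia genes 31 of 40 genes were lower and 4 higher (31 and 4 adjusted over the list alone, adjusted p = 2.0e-15, and adjusted p = 0.0982 with an estimated correlation). Of lens genes 25 of 30 genes were lower and 0 higher (26 and 0 adjusted over the list alone, adjusted p = 2.0e-06, and adjusted p = 0.208 with an estimated correlation). In the cell cycle list 28 of 38 genes were lower and 1 higher (29 and 1 adjusted over the list alone, adjusted p = 3.5e-07, and adjusted p = 0.208 with an estimated correlation). In the erythrocyte list 14 of 20 genes were lower and 4 higher (14 and 4 adjusted over the list alone, adjusted p = 6.2e-06, and adjusted p = 0.0982 with an estimated correlation), with the anion exchanger SLC4A1 (ENSDARG00000012881) 7.08-fold and the haem synthesis gene alas2 5.11-fold lower. For fatty acid oxidation 17 of 33 genes were lower and 2 higher (19 and 2 adjusted over the list alone, adjusted p = 0.0126, and adjusted p = 0.387 with an estimated correlation). The one-carbon list was called lower too, as 15 of 26 genes were lower and 6 higher (16 and 6 adjusted over the list alone, adjusted p = 0.0343, and adjusted p = 0.225 with an estimated correlation). The lists Nrf2 and glutathione (9 higher and 17 lower of 35, 10 and 18 adjusted over the list alone, adjusted p = 0.0964) and cytosolic heat shock (8 higher and 8 lower of 31, 8 and 8 adjusted over the list alone, adjusted p = 0.312) were not called. FOSL1 was at 4.51-fold without replicate 1 of the treated mutant.

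Under iAs, edgeR called 11641 of 23096 genes between genotypes (50.4%), 5208 higher and 6433 lower in the mutant, with 2805 at 2-fold or more. The balance depended on the setting. With library sizes alone 4446 were higher and 7215 lower, with DESeq2 size factors 5460 and 6124, with only the 6 treated libraries 5467 and 5416 and with a replicate block 5275 and 5228. Camera called 16 of 30 lists, and 0 with an estimated correlation (7 at an unadjusted p under 0.05, and 15 with a rank-based camera, smallest adjusted p = 0.0505). Levels of actc1c in the 3 treated mutant libraries were 58.4, 1.33 and 45.5 CPM.

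The last comparison asked whether the response to iAs itself differed between genotypes, as an interaction of genotype and exposure. Genes called higher in both genotypes numbered 4008, of which 1235 were also called in the interaction, and 1074 of these rose more in the mutant. Genes called lower in both numbered 4271, of which 1988 were also called in the interaction, and 1939 of these fell further in the mutant. MT1X rose 2.35 times more in the mutant than in wild type (interaction 1.23, SE 0.13, n = 3 per group), ATF3 5.18 times more (2.37, SE 0.29), hsp70l 7.19 times more (2.85, SE 0.87, adjusted p = 0.0199) and HMOX1 2.42 times more (1.28, SE 0.18). Likewise fabp10a fell 6.54 times further (-2.71, SE 0.27) and CYP1A1 1.64 times further (-0.72, SE 0.11). The interaction for GCLM was -0.18 (SE 0.09, adjusted p = 0.145) and not called, though it was called, at -0.26 with adjusted p = 0.0356, with library sizes alone. The largest interactions upward by the naming rule were CARTPT (ENSDARG00000035852, 3.93), vtg1 (3.85), FOS (ENSDARG00000031683, 3.40), the collagenase mmp13a (2.97) and hsp70l. Downward they were cdh29 (-5.08), cpo (-3.99), crp5 (-3.76), ahsg2 (-3.69) and ABCB11 (ENSDARG00000070078, -3.69). vtg1 was at 2.90 (adjusted p = 0.0795, not called) without replicate 1 of the untreated wild type. hsp70l was at 2.81 (adjusted p = 0.0530, not called) without replicate 2 of the untreated wild type. hsp70l was at 2.73 (adjusted p = 0.0512, not called) without replicate 3 of the untreated wild type. vtg1 was at 5.43 and FOS at 4.16 without replicate 3 of the untreated mutant. hsp70l was at 1.76, FOS at 2.11 and mmp13a at 2.09 without replicate 1 of the treated mutant. ahsg2 was at -4.75 without replicate 2 of the treated mutant. vtg1 was at 2.96, cdh29 at -6.23 and ABCB11 at -4.30 without replicate 3 of the treated mutant.

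Of enterocyte genes, 27 of 34 genes responded lower and 2 higher (30 and 2 adjusted over the list alone, adjusted p = 6.1e-27, and adjusted p = 0.0171 with an estimated correlation) in the mutant, with a median interaction of -1.19. In the cell cycle list 30 of 38 genes responded lower and 0 higher (32 and 0 adjusted over the list alone, adjusted p = 4.3e-15, and adjusted p = 0.0963 with an estimated correlation), with a median of -0.74. It included the ribonucleotide reductase genes RRM2 (ENSDARG00000078069) at -1.23 and RRM1 at -1.15. Of erythrocyte genes 14 of 20 genes responded lower and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 6.8e-11, and adjusted p = 0.0545 with an estimated correlation), with a median of -1.01. SLC4A1 (ENSDARG00000012881) rose 1.98-fold in wild type and fell 4.77-fold in the mutant, and alas2 rose 2.01-fold and fell 2.94-fold. Among neuron and glia genes 23 of 40 genes responded lower and 2 higher (24 and 2 adjusted over the list alone, adjusted p = 7.4e-16, and adjusted p = 0.121 with an estimated correlation), with mbpa at -3.12. Among photoreceptor genes 25 of 46 genes responded lower and 3 higher (32 and 5 adjusted over the list alone, adjusted p = 6.5e-10, and adjusted p = 0.178 with an estimated correlation). Among exocrine pancreas genes 15 of 24 genes responded lower and 1 higher (15 and 1 adjusted over the list alone, adjusted p = 8.4e-09, and adjusted p = 0.275 with an estimated correlation). In acute inflammation 18 of 31 genes responded higher and 0 lower (19 and 0 adjusted over the list alone, adjusted p = 4.0e-09, and adjusted p = 0.262 with an estimated correlation). In p53 and DNA damage 12 of 28 genes responded higher and 3 lower (14 and 3 adjusted over the list alone, adjusted p = 1.2e-04, and adjusted p = 0.275 with an estimated correlation). Of lens genes 22 of 30 genes responded lower and 0 higher (26 and 0 adjusted over the list alone, adjusted p = 4.0e-07, and adjusted p = 0.196 with an estimated correlation). For fatty acid oxidation 16 of 33 genes responded lower and 4 higher (20 and 4 adjusted over the list alone, adjusted p = 0.0189, and adjusted p = 0.399 with an estimated correlation). For one-carbon and SAM metabolism 12 of 26 genes responded lower and 3 higher (13 and 3 adjusted over the list alone, adjusted p = 0.0438, and adjusted p = 0.262 with an estimated correlation). In ribosome biogenesis 9 of 29 genes responded higher and 0 lower (9 and 0 adjusted over the list alone, adjusted p = 2.3e-04, and adjusted p = 0.251 with an estimated correlation). In the leukocyte list 9 of 34 genes responded higher and 3 lower (10 and 4 adjusted over the list alone, adjusted p = 0.0305, and adjusted p = 0.121 with an estimated correlation). In the integrated stress response 14 of 29 genes responded higher and 6 lower (14 and 7 adjusted over the list alone, adjusted p = 0.0354, and adjusted p = 0.466 with an estimated correlation). Among skeletal muscle genes 9 of 38 genes responded higher and 4 lower (10 and 4 adjusted over the list alone, adjusted p = 0.0354, and adjusted p = 0.635 with an estimated correlation). For gluconeogenesis and glucocorticoid targets 9 of 20 genes responded higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.0423, and adjusted p = 0.454 with an estimated correlation). In cholesterol and fatty acid synthesis 8 of 35 genes responded higher and 5 lower (8 and 6 adjusted over the list alone, adjusted p = 0.0438, and adjusted p = 0.635 with an estimated correlation). The lists Nrf2 and glutathione (6 higher and 11 lower of 35, 6 and 13 adjusted over the list alone, adjusted p = 0.223), cytosolic heat shock (5 higher and 4 lower of 31, 5 and 4 adjusted over the list alone, adjusted p = 0.392) and hepatocyte (9 higher and 12 lower of 42, 9 and 14 adjusted over the list alone, adjusted p = 0.240) were not called. In the arsenic transport list 7 of 17 genes responded lower and 2 higher (7 and 2 adjusted over the list alone, adjusted p = 0.0438, and adjusted p = 0.178 with an estimated correlation), and gsto2 rose 19.5-fold in wild type and 5.85-fold in the mutant (interaction -1.74, SE 0.12). The list holds the mutated gene AS3MT itself (interaction -0.83), and a rank-based camera did not call it (adjusted p = 0.0553).

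**Figure D4:**
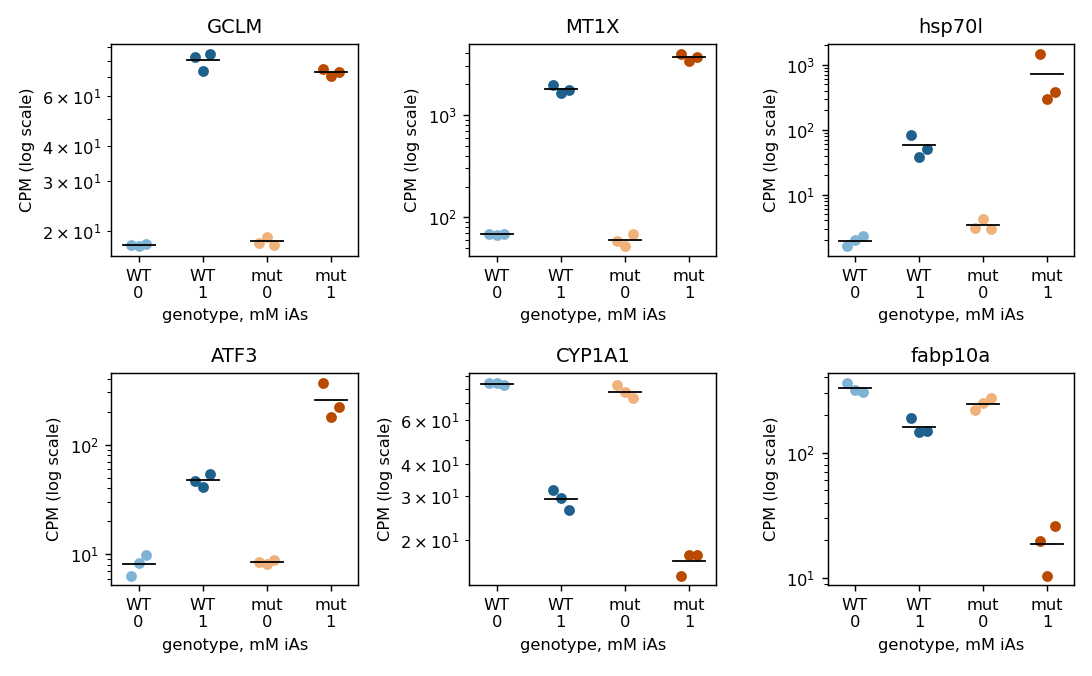
Level in CPM (log axis) of GCLM, MT1X, hsp70l, ATF3, CYP1A1 and fabp10a in each library, by genotype (WT, wild type; mut, as3mt mutant) and iAs dose in mM; points are libraries and lines are means of 3. Treated mutant libraries lie above treated wild type for MT1X, hsp70l and ATF3 and below it for CYP1A1 and fabp10a.

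For the interaction, edgeR called 6984 of 23096 genes (30.2%), 2842 higher and 4142 lower, that is 40.7% higher. With library sizes alone in place of TMM factors, 7210 genes were called, 2110 higher and 5100 lower (29.3% higher), and the median interaction over all genes moved from -0.05 to -0.12. With DESeq2 size factors 3208 were higher and 3751 lower (46.1% higher), with a median of -0.01. Of the genes called in both genotypes and in the interaction, 1074 rose more and 161 less in the mutant, and 1939 fell further and 49 less far. A further 2794 were called in the mutant and not in wild type, 553 in wild type and not in the mutant, 313 in both with opposite direction, and 101 in neither. Camera called 18 of 30 lists, and 1 (enterocyte) with an estimated correlation. Without replicate 2 of the treated wild type, 12 lists were called. Median, mean and test differed in sign for 2, 3, 7, 4 and 4 lists in the 5 comparisons in the order given here, and 0 of these lists were called.

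Across genes, the responses of the 2 genotypes correlated (Pearson 0.717, Spearman 0.703 over 23096 genes, which are not independent replicates), with a major-axis slope of 1.84 for mutant on wild type. The comparisons share no library. Genes called higher in both numbered 4008, against 1624 for independent lists, and genes called lower in both 4271, against 1669. Among the 1695 genes called in wild type at 2-fold or more, 1608 changed in the same direction in the mutant and 958 (56.5%) by more. Over these 1695 genes the median ratio of the mutant to the wild-type log2 fold change was 1.104.

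**Figure D5:**
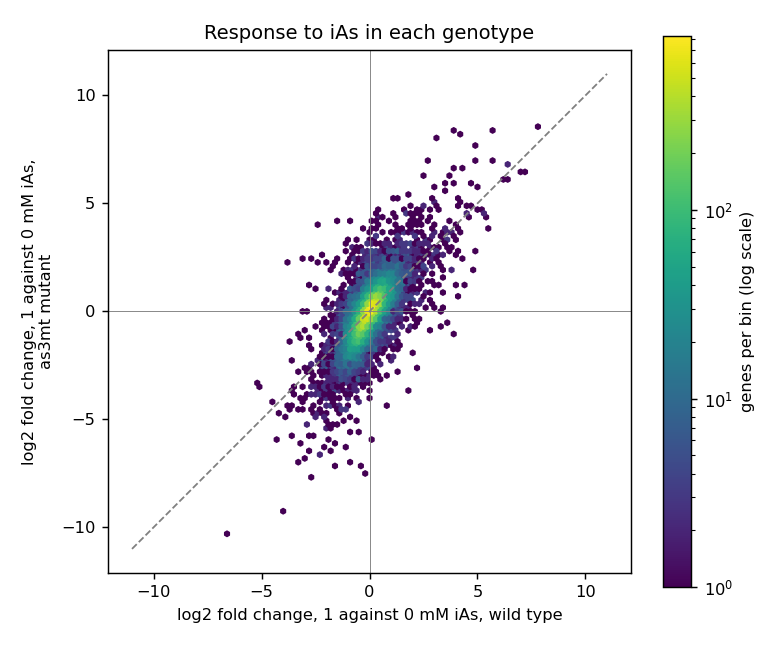
Log2 fold change between 1 and 0 mM iAs in wild type (horizontal) against the as3mt mutant (vertical) for the 23096 tested genes; colour gives the number of genes per hexagon on a log scale and the dashed line marks equal change. The cloud is steeper than the dashed line (major-axis slope 1.84).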

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

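Tests chosen after the result they bear on was seen are those of the scaling, of single treated mutant libraries, of clock genes at 1 mM and of other splits of the libraries.

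The response to iAs differed between the genotypes for 6984 genes and 18 gene lists, by the interaction test, and for 1 list with an estimated correlation and 12 lists without replicate 2 of the treated wild type. A different library depth as the whole source was predicted to bring the major-axis slope of mutant on wild-type changes near 1. With all libraries thinned to the smallest total the slope lay between 1.83 and 1.84 over 5 thinnings. Genes called in wild type at 2-fold or more had a median ratio of 1.104. But thinning leaves the expected fold changes as they are, so the slope could not show an effect of depth. Calls were not recounted after thinning. Totals ran from 28909467 to 43759270 counts over the wild-type libraries and from 32934791 to 38382990 over the mutant ones. The mean total was higher in the mutant without iAs and lower with it. These totals argue against greater depth of the mutant libraries as the source of the 14695 calls in the mutant against 10354 in wild type. A scaling error of the treated mutant libraries would enlarge changes in 1 direction and shrink them in the other, but 87.0% of the rises (1074 of 1235) and 1939 of the 1988 falls called in both genotypes and in the interaction were larger in the mutant. Nor did 1 treated mutant library carry it, since the slope was 1.83, 1.93 and 1.90 without each of the 3. Still open are the as3mt genotype and the strain background, while a smaller effect of depth on the calls was not tested. Genotype and strain went together in every library, so that a biological reading may refer to either, and neither was tested.

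Single genes with a different response by the interaction test, on the log2 scale, were AS3MT (-0.83), HMOX1 (1.28), MT1X (1.23), ATF3 (2.37), CYP1A1 (-0.72) and fabp10a (-2.71). Chaperone gene hsp70l had an interaction of 2.85, with the 3 treated mutant libraries at 1493, 296 and 388 CPM. Those with the largest interactions were CARTPT (3.93), vtg1 (3.85), FOS (3.40), mmp13a (2.97), cdh29 (-5.08), cpo (-3.99), crp5 (-3.76), ahsg2 (-3.69) and ABCB11 (-3.69). By library the treated mutant held FOS at 108, 13.9 and 26.7 CPM and vtg1 at 4.15, 20.7 and 44.1 CPM.

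The response of the Nrf2 and glutathione list was not called different in the mutant, with a median interaction of -0.15 (adjusted p = 0.223 by camera). Of its members, the 28 that rose in wild type had a median interaction of -0.23. Selecting large wild-type responses could pull the interaction down, so random sets of genes matched on the wild-type change were drawn 10000 times, with 20 candidate genes per member. Their medians centred on 0.01, with a 95% range of -0.37 to 0.41. These sets carry the selection together with any larger response of the mutant, so they cannot show the effect of selection alone. At percentile 13.8 the list may be no different from other genes with the same wild-type change, and no separate biological explanation was tested.

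Some clock and light-induced genes differed between the untreated genotypes, with 5 of 38 clock genes higher, 10 lower and 23 not called, and the list was not called (adjusted p = 0.465). Different light or time of day at collection may lower light-induced genes, and 2 of 4 were called lower, lonrf1 (-0.62) and cry-dash (-0.48), against -0.29 for NEIL1 and 0.06 for cpdp. Variants of the mutant's strain against the reference would act with and without iAs, and 66.7% of the 15 called clock genes (10) kept direction and call at 1 mM. Neither value decides, so light, time, strain variants and genotype cannot be told apart, since each untreated group came from 1 genotype and the labels give 1 age at collection for all.

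Splitting the same 6 libraries in the other ways gave at most 0 genes called by edgeR in each of the 4 comparisons between groups, where the real splits gave 10354, 14695, 3110 and 11641 (at most 1090, 879, 1315 and 1163 at an unadjusted p under 0.05, and DESeq2 was not run on the splits). In each, the 1 split of 10 that gave as many genes was the real one itself, and 10 splits are too few for a share under 0.05. Every other split mixes both groups, whose difference then widens the spread and holds down the calls. These splits therefore leave open whether chance could give the real counts. For the interaction, 2 of 60 splits drawn from 200, the real one among them, gave at least as many genes as the real 6984. The other, with 10432 genes, exchanged the genotype labels of all treated libraries and so follows the structure of the groups. All remaining splits mix the genotypes within a group, and the difference between genotypes then widens the spread, so these splits leave open whether chance could give 6984 genes.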

How the results depend on the processing

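All tests here were planned before the data were examined. In the order iAs in wild type, iAs in the mutant, untreated genotypes, treated genotypes and interaction, the counts of called genes stayed within 1.5 times under every scaling, filter, tool and choice of libraries tried. With DESeq2 in place of edgeR they were 10234, 14667, 3400, 11572 and 7083, and with no filter on low counts 10158, 14753, 3177, 11707 and 6823. Fits of only the 6 libraries compared do not share the spread of all groups. They called more genes for iAs in wild type (10862 against 10354) and between untreated genotypes (3530 against 3110). They called fewer for iAs in the mutant (13976 against 14695) and between treated genotypes (10883 against 11641). At 2-fold or more they were 1695, 4747, 794, 2805 and 1791, as that alternative only takes a part of the called genes. Camera with an estimated correlation called 4, 3, 0, 0 and 1 lists in place of 21, 18, 7, 16 and 18. In the comparisons with 0, 3 and 7 lists had an unadjusted p under 0.05, and a rank-based camera called 7 and 15. Leaving out each library in turn gave 8555 to 9628 genes and 20 to 23 lists for iAs in wild type, 13660 to 14305 genes and 18 to 20 lists for iAs in the mutant, 2097 to 2771 genes and 6 to 8 lists between untreated genotypes, 10225 to 11256 genes and 14 to 17 lists between treated genotypes and 5993 to 7140 genes and 12 to 18 lists for the interaction. Between untreated genotypes the 2097 genes came without replicate 2 of the untreated mutant. Without replicates 1 and 3 of that group 2348 and 2771 were called, and without each untreated wild-type library 2189, 2165 and 2204. The drop was thus not particular to 1 library. For the interaction the 12 lists came without replicate 2 of the treated wild type, and with any other library left out 14 to 18 were called. The correlation of the responses, 0.717 over all genes, was 0.683 to 0.703 with a library left out and 0.813 over genes with a mean of at least 5 CPM, and the cause was not tested. The genes picked by the naming rule were each followed in every comparison. Under an alternative, 17765 of their values stayed called or stayed not called, 524 lost the call and 229 gained it. For the lists these were 1389, 118 and 23. No value that was called in the main fit or in the alternative changed direction. Values called in neither could change direction, as did the arsenic transport list in wild type with the rank-based camera.

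Libraries of different groups carry the same replicate numbers. The 12 correlations of their deviations ran from -0.026 to 0.069, with 0 over 0.1 and 5 best with their own number. Between untreated and treated libraries they were 0.0065, 0.037 and 0.069 in wild type and -0.0087, 0.0064 and -0.026 in the mutant. The rest set wild type against the mutant, which came from another background. No strong pairing was seen, but 3 libraries per group cannot show that the numbers mark no pairs. With the number as a replicate block, 10008, 14479, 3189, 10503 and 6685 genes and 20, 18, 9, 15 and 18 lists were called, with a correlation of the responses of 0.717. The planned check of genes near as3mt was not run. Depth limits mainly the genes at a few counts. Folds are given as bounds or with counting intervals only where a group had at most 3 counts. Folds on slightly more counts are fitted values without an interval. Examples are lepb in the mutant, with 7 counts over the untreated libraries, and MEP1B in wild type, with 15 over the treated ones.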

Other observations

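Genes and gene groups in this part were chosen after the main results were seen, while the list of hypoxia-inducible factor targets was written down before it was tested. The leptin gene lepb, a known target of low oxygen in fish, went from 2 counts over the 3 untreated wild-type libraries to 580 over the treated ones, a ratio of 247 (exact 95% counting interval 68.2 to 2048). In the mutant lepb rose 394-fold from 7 counts over the 3 untreated libraries, with 40.7, 14.3 and 23.1 CPM in the treated libraries. The hypothesis was that targets of the hypoxia-inducible factor rise with iAs as a group. Of 32 measured targets, 0 of them in another list, 16 rose and 6 fell in wild type, with a median of 0.24, and 23 rose and 6 fell in the mutant, with a median of 0.63. In the mutant the prolyl hydroxylase genes P4HA1 and P4HA2 changed by 2.96 and 2.34, ANKRD37 by 3.66, the adrenomedullin gene ADM (ENSDARG00000069027) by 3.82 and the glycolysis regulator PFKFB3 by 2.08. Members that fell included the glucose transporter SLC2A1 (ENSDARG00000001437) at -2.49, the carbonic anhydrase ca9 at -1.63 (-0.72 in wild type) and ALDOC (ENSDARG00000057661) at -1.35. Camera gave p = 0.0257 in wild type and 5.9e-08 in the mutant with the preset correlation, and p = 0.202 and 0.0114 with an estimated one, so the group may rise in the mutant while wild type does not decide (p = 0.202). The interaction had 16 targets higher and 3 lower (p = 1.6e-10, and p = 0.00490 with an estimated correlation).

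Some genes were read in 1 genotype almost alone. All 3 gene IDs with the symbol GGACT had 0 or 1 counts in each wild-type library. In the untreated mutant ENSDARG00000038248 had 323, 331 and 258 counts, at least 282-fold more than wild type against a floor of 3 counts over the group. The other IDs had 135, 165 and 109 counts (ENSDARG00000070579) and 194, 213 and 169 (ENSDARG00000070581). Of the 2 gene IDs with the symbol CCDC134, ENSDARG00000103285 had 1 or 2 counts in each mutant library and 328 to 552 in each wild-type library. The other, ENSDARG00000030508, was higher in the mutant by 1.13 (log2, SE 0.13) without iAs and 0.67 (SE 0.13) with it.

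Some genes varied between the treated mutant libraries. Levels of hsp70.1 were 127, 28.5 and 35.4 CPM, and those of actc1c were 58.4, 1.33 and 45.5 CPM, against 22.7, 21.3 and 22.9 in the untreated mutant.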
